A study of Mus musculus with 24 samples.

How the data were processed

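The samples are libraries of messenger RNA from mouse kidney, taken from microdissected proximal tubules or from endothelial cells isolated with CD31 microbeads, after sham surgery or ischemic injury in males and females. Per the labels, poly-A libraries were sequenced on an Illumina NextSeq and quantified by the authors with Salmon 0.13.1 against mouse transcripts of GRCm38. Each of the 24 deposited quantification files gives, per transcript, the estimated count (expected counts, not normalized), the TPM (transcript abundance scaled within the library) and the effective length in bases. The 8 deposited comparison tables were made by the authors with DESeq2, version not stated, and give a log2 fold change, its error and a p-value adjusted for multiple tests (adjusted p) per gene. Many of the deposited log2 fold changes lie near 0 with tiny errors, a form that shrinkage gives, so these values are used here only beside the refitted ones.

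Estimated counts were summed per gene and rounded. The files list 136202 transcripts, of which 134907 have the same versioned identifier in GENCODE M21, and 53392 genes, of which 53355 were found there. Sham male tubule replicate 3 was sequenced as 2 libraries of 1 sample, with 21192097 and 21054189 estimated reads, and these were summed, as the labels say the authors combined them. The 2 libraries differed by a chi-square of 255 per degree of freedom, against 25.7 to 534 between other libraries of a group, so they did not agree within sampling noise. This left 23 libraries in 8 groups: 12 of tubule and 11 of endothelial cells. Depth ran from 32592452 to 54906864 estimated reads, and a gene with no read in any library of a group lies below 0.0212 to 0.0317 CPM at a floor of 3 counts over the group. Floors and their folds cover counting error only, not the spread between mice.

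Each isolation was fitted with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr filter (minimum count 10, minimum total 15), 1 mean per group, and the quasi-likelihood F-test. P-values were adjusted by Benjamini-Hochberg over all genes tested (18369 in tubule, 19910 in endothelial libraries, 21206 in a fit of both), and a gene is called at an adjusted p under 0.05. The SE is the size of the log2 change divided by the root of the F statistic. The common biological coefficient of variation was 0.3923 in tubule, 0.4469 in endothelial and 0.4471 in both, with 8, 7 and 15 residual degrees of freedom. The 12 comparisons were injury against sham in each sex, male against female after sham and after injury, and the sex difference in the injury response, in each isolation, then endothelial against tubule in sham and in the injury response, with equal weight to the sexes.

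In all, 40 gene lists, 11 of them cell type markers, were fixed from general knowledge and tested with limma 3.58.1: camera on voom values with a preset correlation of 0.01, and again with the correlation estimated per list, for lists with at least 3 tested members. Camera p-values were adjusted over the lists of a comparison. Members are counted as called over all genes and, separately, with the adjustment over the list alone. A symbol shared by 2 gene records (Ddit3, Aldoa, Atp5o) counts with both. A marker score of a library is the mean log2 CPM (prior count 2) of a marker list minus the mean over the libraries of that isolation. Several lists share members with others, and the kidney itself expresses members of most of them.

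Genes named in the text were chosen by a rule. It takes, per comparison, the 6 largest rises and 6 largest falls among called protein-coding genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries (interactions without this last condition). With 3 against 3 libraries, chance gives no overlap for 10% of genes. It adds up to 4 members with the smallest adjusted p per list described, 12 fixed genes (Havcr1, Lcn2, Lrp2, Slc34a1, Pecam1, Cdh5, Umod, Xist, Ddx3y, Eif2s3y, Kdm5d, Uty), and the genes weighed in the closing section. CT010467.1 falls outside the rule and was chosen after its values were seen. The grouping, comparisons, tests, naming rule and alternatives were set before the data were examined, except the alternatives marked as chosen after seeing the data.

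The alternatives were RLE in place of TMM normalization, no low-count filter, the DESeq2 1.42.0 Wald test, length offsets from the effective lengths, only the groups compared in the fit, the tubule marker score as a covariate in endothelial fits, a replicate block, 1 of the 2 technical libraries alone, the estimated correlation, and leaving out each library in turn. Chosen after seeing the data were the distal marker score in tubule fits, the endothelial marker score in endothelial fits, and leaving out injured male tubule replicate 3 or endothelial replicate 2 from comparisons they are not part of. The fits were tested on simulated data with 100 genes changed at each fold, drawn from genes with a mean of at least 5 CPM. Counts were simulated independently per gene with no outlying library, so the shares do not cover low genes or such libraries. At a 2-fold change 33% were recovered for injury in female and 41% in male tubules, and 10% for the tubule sex difference in response. The shares were 3% in female and 3% in male endothelial libraries, and 61% between the isolations. At a 4-fold change the shares were 87%, 86%, 68%, 47%, 75% and 97%, with no wrong direction and 0 to 7 unchanged genes called. Gene list tests with the preset correlation on a list of unchanged genes gave p = 0.00428 in male endothelial libraries, a false call at 0.05, 0.0707 in male tubules and 0.0986 to 0.952 in the others. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

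Against the deposited tables of the authors, which hold 24169 genes each, the log2 changes correlated at 0.21 to 0.84 (Pearson) and 0.69 to 0.92 (Spearman) over the genes tested here, which are not independent replicates. No gene called in both had opposite directions. Neither batches nor flow cells are given per library in the labels, so no batch term was fitted.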

Results

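Messenger RNA was sequenced from kidneys of FVB mice, an inbred strain, after sham surgery or ischemic acute kidney injury, in males and females. Proximal tubules were microdissected, and endothelial cells were taken with microbeads against CD31, the protein of Pecam1. The 8 groups held 3 libraries each, except the sham female endothelial group, which held 2. The protocol in the labels describes RNA from 3 males and 3 females per group, so replicates of a group are taken as separate mice. Endothelial and tubule libraries share title numbers, and the labels do not say whether a shared number means the same mouse. The libraries held 32592452 to 54906864 estimated reads, of which 7.06 to 16.2% lay in mitochondrial genes. Sham male tubule replicate 3 stood apart in composition: a single gene, CT010467.1, took 8.53% of its reads, and protein-coding genes took 86.8%. Expression is given as CPM, counts scaled by normalized library size, as mean ± SD with n = 3, and log2 changes ± SE from the edgeR fit, unless another n or source is named. Gene positions are those of GRCm38 in GENCODE M21.

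The first question was what injury did to proximal tubules of males. Of 18369 genes tested, 1939 rose and 1549 fell, together 19.0%. Most tested members of the tubular injury list rose, and most tested proximal tubule markers, organic ion transporters and gluconeogenesis genes fell. Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), went from 235 ± 68.6 to 2893 ± 689.7 CPM (3.62 ± 0.24, adjusted p = 8.0e-05). The injury marker Havcr1, encoding KIM-1 (chromosome 11, 46735080 to 46779578), went from 4.19 ± 0.954 to 204 ± 150.2 CPM (5.61 ± 0.83, adjusted p = 0.0024). Lcn2, encoding lipocalin 2 (chromosome 2, 32384633 to 32388252), went from 2.51 ± 2.39 to 394 ± 179.9 CPM (7.29 ± 1.04, adjusted p = 0.0020). Lrp2, encoding the endocytic receptor megalin (chromosome 2, 69424340 to 69586065), fell from 3400 ± 579 to 939.6 ± 273 CPM (-1.86 ± 0.22, adjusted p = 9.4e-04). Under the naming rule, the largest rises were those of Krt20, a keratin (chromosome 11, 99428403 to 99438150, 12.09 ± 1.60), Flnc, Saa1, Gm3776 and Adra1b, with log2 changes between 7.33 and 12.09. Tpsab1, a mast cell tryptase, had no read in the sham males and was at least 268-fold higher after injury. Ido2, of tryptophan breakdown, fell (-3.01 ± 0.37), and the other falls the rule names were Slc7a12, Slc22a13, Myom3, Col19a1 and Nat8f3 (-3.39 to -2.65). Saa1, Gm3776, Tpsab1 and Nat8f3 belong to families of near-identical genes, so the share of reads given to each member is uncertain.

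In the tubular injury list of males, 19 of 24 tested members rose, 0 fell and 5 did not pass (21 and 0 adjusted over the list alone). Plin2 (4.23 ± 0.55, adjusted p = 0.0013), Fgg (4.80 ± 0.62, adjusted p = 0.0013) and the adhesion molecule Vcam1 (3.48 ± 0.45, adjusted p = 0.0015) were among its members beside Spp1 (camera adjusted p = 1.0e-13, adjusted p = 0.098 with an estimated correlation). Of proximal tubule markers, 0 of 26 tested members rose, 14 fell and 12 did not pass (0 and 15 adjusted over the list alone). Cubn (-1.50 ± 0.20, adjusted p = 0.0016), which encodes the partner receptor of megalin, and Slc27a2 (-1.02 ± 0.15, adjusted p = 0.0026) fell (camera adjusted p = 2.4e-06, adjusted p = 0.16 with an estimated correlation). Organic anion and cation transporters moved the same way: 0 of 20 tested members rose, 11 fell and 9 did not pass (2 and 13 adjusted over the list alone). Among them were Slc22a6 (-0.89 ± 0.18, adjusted p = 0.0091) and Slc22a2 (-0.83 ± 0.12, adjusted p = 0.0024) (camera adjusted p = 1.7e-04, adjusted p = 0.11 with an estimated correlation). For gluconeogenesis, 0 of 9 tested members rose, 6 fell and 3 did not pass (0 and 7 adjusted over the list alone). Pcx (-0.73 ± 0.15, adjusted p = 0.010) was among its members (camera adjusted p = 3.9e-04, adjusted p = 0.16 with an estimated correlation). Of amino acid transporters, 4 of 18 tested members rose, 8 fell and 6 did not pass (5 and 9 adjusted over the list alone): Slc38a2 (3.13 ± 0.45, adjusted p = 0.0022) was higher and Slc6a20b (-1.46 ± 0.15, adjusted p = 3.7e-04) lower (camera adjusted p = 0.26). Among fatty acid oxidation genes, 0 of 25 tested members rose, 4 fell and 21 did not pass (1 and 4 adjusted over the list alone). Acadm (-0.78 ± 0.17, adjusted p = 0.013) was among its members (camera adjusted p = 0.034, adjusted p = 0.57 with an estimated correlation). Among genes of the tricarboxylic acid cycle and respiratory chain, 0 of 25 tested members rose, 4 fell and 21 did not pass (0 and 4 adjusted over the list alone) (camera adjusted p = 0.058), Idh2 (-0.67 ± 0.10, adjusted p = 0.0027) with the smallest p.

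Members of stress and inflammation lists rose in the same tubules. For NRF2 targets and iron handling, 9 of 21 tested members rose, 1 fell and 11 did not pass (11 and 2 adjusted over the list alone). Gsta2 (2.43 ± 0.23, adjusted p = 2.9e-04), the ferritin gene Fth1 (1.13 ± 0.12, adjusted p = 4.0e-04) and Srxn1 (1.82 ± 0.20, adjusted p = 5.8e-04) were among its members (camera adjusted p = 1.7e-04, adjusted p = 0.18 with an estimated correlation). For p53 targets, 7 of 16 tested members rose, 0 fell and 9 did not pass (9 and 0 adjusted over the list alone). The cell cycle inhibitor gene Cdkn1a (5.03 ± 0.99, adjusted p = 0.0087) and the death receptor gene Fas (2.48 ± 0.45, adjusted p = 0.0061) were among its members (camera adjusted p = 0.0024, adjusted p = 0.41 with an estimated correlation). Cdkn1a read 659.8, 589 and 23.4 CPM in injured male replicates 1, 2 and 3, and at most 20.8 in the sham males. For the integrated stress and ER stress response, 9 of 19 tested members rose, 0 fell and 10 did not pass (10 and 1 adjusted over the list alone). Psat1 (2.65 ± 0.37, adjusted p = 0.0020) and Xbp1 (1.61 ± 0.32, adjusted p = 0.0095) were among its members (camera adjusted p = 0.036, adjusted p = 0.39 with an estimated correlation). For chemokines and NF-kB targets, 12 of 24 tested members rose, 0 fell and 12 did not pass (16 and 0 adjusted over the list alone). The cytokine gene Il34 (2.41 ± 0.38, adjusted p = 0.0034) and Nfkb1 (1.53 ± 0.23, adjusted p = 0.0027) were among its members (camera adjusted p = 5.8e-08, adjusted p = 0.39 with an estimated correlation). For extracellular matrix and TGF-beta targets, 8 of 24 tested members rose, 0 fell and 16 did not pass (9 and 0 adjusted over the list alone). The basement membrane collagen gene Col4a1 (1.21 ± 0.21, adjusted p = 0.0049) was among its members (camera adjusted p = 7.9e-05, adjusted p = 0.39 with an estimated correlation). For autophagy and lysosome, 6 of 15 tested members rose, 0 fell and 9 did not pass (7 and 0 adjusted over the list alone). Ctsl (3.09 ± 0.41, adjusted p = 0.0015) and Ctsb (1.29 ± 0.13, adjusted p = 3.0e-04), both encoding cathepsins were among its members (camera adjusted p = 0.0038, adjusted p = 0.39 with an estimated correlation). MHC class II genes went down: 0 of 7 tested members rose, 4 fell and 3 did not pass (0 and 6 adjusted over the list alone). Cd74 (-2.35 ± 0.45, adjusted p = 0.0077), which encodes the invariant chain was among its members (camera adjusted p = 3.9e-04, adjusted p = 0.24 with an estimated correlation). Of cell cycle genes, 6 of 27 tested members rose, 0 fell and 21 did not pass (6 and 1 adjusted over the list alone). Mcm4 (1.25 ± 0.19, adjusted p = 0.0028) and Pcna (0.86 ± 0.17, adjusted p = 0.0080) rose (camera adjusted p = 0.012, adjusted p = 0.41 with an estimated correlation).

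Markers of other cells moved too in the injured male tubules. For neutrophil markers, 5 of 9 tested members rose, 0 fell and 4 did not pass (7 and 0 adjusted over the list alone) (camera adjusted p = 0.0095, adjusted p = 0.47 with an estimated correlation). The neutrophil score, a mean log2 deviation from all tubule libraries, was 3.00 and 2.33 in injured male replicates 1 and 2 but -0.20 in replicate 3. That replicate also had the lowest score of thick ascending limb and distal markers, -1.34, and correlated at 0.971 and 0.975 across genes with the others of its group, which correlated at 0.996 with each other. Distal markers went both ways: of thick ascending limb and distal markers, 1 of 11 tested members rose, 2 fell and 8 did not pass (2 and 2 adjusted over the list alone) (camera adjusted p = 0.68). The potassium channel gene Kcnj1 (-1.54 ± 0.33, adjusted p = 0.012) and the collecting duct water channel gene Aqp3 (-1.25 ± 0.31, adjusted p = 0.020) fell. Umod (1.19 ± 0.41, adjusted p = 0.063) did not pass here, while the authors' deposited table gives 1.00 ± 0.46 for Umod with an adjusted p = 0.026. In the authors' deposited table for this comparison 4101 genes passed the same threshold, 2915 of them called here and none in the opposite direction, and Havcr1 changed by 5.46 ± 0.68 (± as deposited, SE or posterior SD). DESeq2 called 5162 genes here. Fitting the 6 libraries alone left 154 genes, the distal marker score as a covariate (chosen after seeing the data) gave 5983 (2761 higher, 3222 lower), and length offsets gave 2115. Leaving out injured replicate 1, 2 or 3 gave 1168, 953 or 8203 genes (without replicate 3, 3853 higher and 4350 lower), and leaving out sham replicate 1, 2 or 3 gave 1669, 1285 or 1581.

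**Figure D1:**
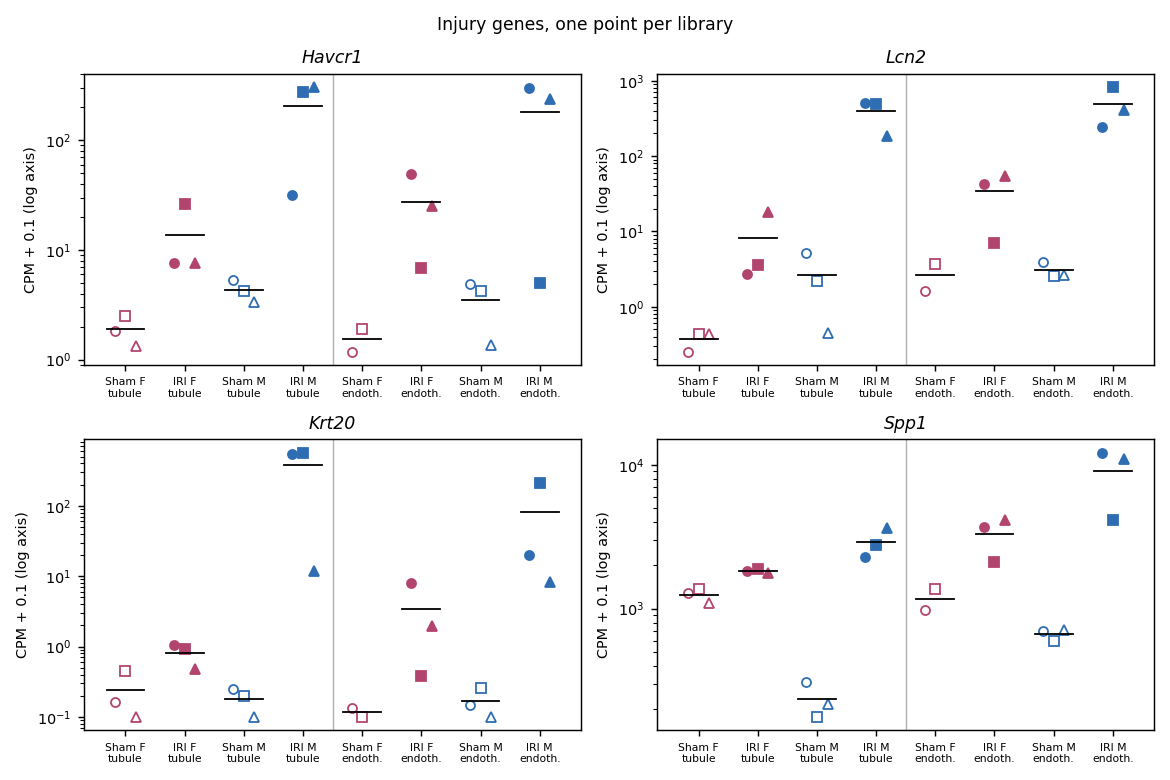
CPM + 0.1 (log axis) of 4 injury-related genes in each library, by group; open points are sham, filled points injured, pink female, blue male, shapes give the replicate number and black lines the group mean. Havcr1 is at 204 ± 150.2 CPM in injured male tubules against 13.7 ± 10.8 in injured female tubules.

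In tubules of females, 2 genes passed the test after injury. Casr, the calcium-sensing receptor gene (chromosome 16, 36493696 to 36562141), rose from 17.8 ± 1.37 to 56.9 ± 2.41 CPM (1.67 ± 0.18, adjusted p = 0.027). Mecom, a transcription factor gene (chromosome 3, 29951296 to 30548008), rose from 18.0 ± 0.664 to 49.5 ± 3.58 CPM (1.46 ± 0.18, adjusted p = 0.040). Injury genes had positive log2 changes that did not pass: Havcr1 (2.92 ± 0.76, adjusted p = 0.15), Lcn2 (4.83 ± 1.06, adjusted p = 0.093) and the chaperone gene Clu (2.08 ± 0.43, adjusted p = 0.082). For the tubular injury list, 0 of 24 tested members rose, 0 fell and 24 did not pass (7 and 0 adjusted over the list alone) (camera adjusted p = 7.4e-06, adjusted p = 0.22 with an estimated correlation). Markers of other nephron segments were high in the same libraries: the distal marker score was 1.01 to 1.14 in the injured females against 0.06 to 0.16 in the sham females. For collecting duct markers, 0 of 11 tested members rose, 0 fell and 11 did not pass (11 and 0 adjusted over the list alone). The sodium channel subunit gene Scnn1g (2.03 ± 0.40, adjusted p = 0.082) and the water channel gene Aqp2 (3.17 ± 0.82, adjusted p = 0.15) were among its members (camera adjusted p = 1.2e-10, adjusted p = 0.24 with an estimated correlation). For thick ascending limb and distal markers, 0 of 11 tested members rose, 0 fell and 11 did not pass (4 and 0 adjusted over the list alone). Umod (2.04 ± 0.42, adjusted p = 0.082) of uromodulin and Cldn16 (1.85 ± 0.33, adjusted p = 0.063) were among its members (camera adjusted p = 3.4e-05, adjusted p = 0.22 with an estimated correlation). Proximal tubule markers had a median of -0.35: 0 of 26 tested members rose, 0 fell and 26 did not pass (0 and 0 adjusted over the list alone) (camera adjusted p = 2.8e-06, adjusted p = 0.22 with an estimated correlation). For chemokines and NF-kB targets, 0 of 24 tested members rose, 0 fell and 24 did not pass (5 and 0 adjusted over the list alone). Socs3 (3.02 ± 0.58, adjusted p = 0.072) was among its members (camera adjusted p = 7.1e-05, adjusted p = 0.59 with an estimated correlation). For cell cycle genes, 0 of 27 tested members rose, 0 fell and 27 did not pass (6 and 0 adjusted over the list alone). Mcm4 (0.80 ± 0.19, adjusted p = 0.11) was among its members (camera adjusted p = 2.8e-06, adjusted p = 0.22 with an estimated correlation).

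An unadjusted p under 0.05 was reached by 2032 genes (11.1%) in this female comparison, and DESeq2 called 635. The authors' deposited table has 497 genes past the threshold, including Casr and Mecom. Genes that did not pass here also passed in that table. They include Lcn2 (4.29 ± 0.85, adjusted p = 1.5e-05), Havcr1 (1.925 ± 0.793, adjusted p = 0.024) and Umod (1.76 ± 0.48, adjusted p = 0.0015), with ± as deposited. The count became 0 with length offsets, the distal marker covariate (chosen after seeing the data) or any of the 6 female libraries left out, 158 without the low-count filter, and 1167 with the 6 libraries fitted alone. Leaving out injured male replicate 3, which is not in either group, gave 501.

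Sham tubules of males and females differed in 595 genes higher in males and 470 higher in females. Kdm5d, on the Y chromosome, was at 17.7 ± 3.37 CPM in males and 0.230 ± 0.151 in females (6.29 ± 0.61, adjusted p = 1.6e-04). Xist, the RNA that silences an X chromosome, was at 86.1 ± 30.8 CPM in females and 0.169 ± 0.292 in males (-8.99 ± 0.83, adjusted p = 1.1e-04). Of male-biased kidney genes, 15 of 17 tested members were higher in males, 0 higher in females and 2 did not pass (17 and 0 adjusted over the list alone) (camera adjusted p = 1.7e-27, adjusted p = 0.021 with an estimated correlation). Cyp4a12a, an omega-hydroxylase gene, stood at 392 ± 47.9 against 12.2 ± 8.29 CPM, and Odc1, the gene of the first enzyme of polyamine synthesis, at 2877 ± 315 against 674 ± 49.0 (2.09 ± 0.16, adjusted p = 3.4e-05). Gstp3 (8.74 ± 0.65), Sorcs1 (7.40 ± 0.88) and Ugt2b37 (6.40 ± 0.88) were also higher in males. Gvin1 was at least 532-fold higher, with no read in the sham females. Ugt1a2, a glucuronosyltransferase gene (chromosome 1, 88200601 to 88218997), stood at 2392 ± 780.4 CPM in females and 3.02 ± 2.46 in males (-9.63 ± 0.70, adjusted p = 2.1e-05). Other genes higher in females were Atp13a4, the prolactin receptor gene Prlr, Slc22a29, Bhmt of betaine metabolism and Hdc of histamine synthesis (-9.03 to -4.83). Gvin1, Ugt1a2, Ugt2b37, Slc22a29 and Cyp4a12a have close paralogs, so their single-gene values are uncertain.

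Of female-biased kidney genes, 2 of 13 tested members were higher in males, 3 higher in females and 8 did not pass (3 and 7 adjusted over the list alone) (camera adjusted p = 0.049, adjusted p = 0.55 with an estimated correlation). Cyp2a4 (2.39 ± 0.27, adjusted p = 3.8e-04) and Slco1a6 (2.03 ± 0.29, adjusted p = 0.0016) were higher in males here, Kynu (-3.23 ± 0.55, adjusted p = 0.0051) in females. Among MHC class II genes, 2 of 7 tested members were higher in males, 0 higher in females and 5 did not pass (6 and 0 adjusted over the list alone). H2-Ab1 (2.95 ± 0.41, adjusted p = 0.0014) was among its members (camera adjusted p = 1.9e-05, adjusted p = 0.15 with an estimated correlation). For organic anion and cation transporters, 4 of 20 tested members were higher in males, 4 higher in females and 12 did not pass (7 and 5 adjusted over the list alone) (camera adjusted p = 0.81). Slc22a30 (4.54 ± 0.53, adjusted p = 4.7e-04) was on the male side and Abcb1b (-2.84 ± 0.31, adjusted p = 2.7e-04) on the female side. Gluconeogenesis genes Pck1 (-1.11 ± 0.21, adjusted p = 0.0095) and G6pc (-1.24 ± 0.26, adjusted p = 0.015) were higher in females, with 0 of 9 tested members higher in males, 2 higher in females and 7 not passed (1 and 3 adjusted over the list alone) (camera adjusted p = 0.050). Of chemokines and NF-kB targets, 2 of 24 tested members were higher in males, 0 higher in females and 22 did not pass (10 and 0 adjusted over the list alone) (camera adjusted p = 0.0013, adjusted p = 0.85 with an estimated correlation). For X-linked genes that escape inactivation, 0 of 9 tested members were higher in males, 3 higher in females and 6 did not pass (0 and 6 adjusted over the list alone) (camera adjusted p = 0.0012, adjusted p = 0.053 with an estimated correlation). For Y-linked genes, 4 of 4 tested members were higher in males, 0 higher in females and 0 did not pass (4 and 0 adjusted over the list alone) (camera adjusted p = 5.6e-06, adjusted p = 0.053 with an estimated correlation). Esr1, the estrogen receptor gene, was higher in males (2.22 ± 0.27, adjusted p = 5.5e-04). The authors' deposited table has 1820 genes past the threshold, 927 of them called here. DESeq2 called 1950 genes and the 6 libraries alone 1709. Leaving out sham female replicate 1, 2 or 3 gave 623, 653 or 621, sham male replicate 1 or 2 gave 556 or 550, and injured male replicate 3, outside the groups, gave 2626.

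Injured tubules of males and females differed in 2345 genes higher in males and 1926 higher in females. Injury genes were higher in males: Havcr1 stood at 204 ± 150.2 against 13.7 ± 10.8 CPM (3.90 ± 0.76, adjusted p = 0.0057) and Krt20 at 374 ± 314 against 0.719 ± 0.297 (9.01 ± 1.33, adjusted p = 0.0015). Of the tubular injury list, 14 of 24 tested members were higher in males, 0 higher in females and 10 did not pass (21 and 0 adjusted over the list alone). Tnfrsf12a (4.36 ± 0.54, adjusted p = 6.4e-04) was among its members (camera adjusted p = 2.2e-11, adjusted p = 0.080 with an estimated correlation). The stress genes Hmox1 (3.27 ± 0.39, adjusted p = 5.4e-04) of heme oxygenase, Cdkn1a (5.63 ± 1.02, adjusted p = 0.0042) and the transcription factor genes Fosl1 (8.84 ± 1.46, adjusted p = 0.0025) and Myc (3.54 ± 0.73, adjusted p = 0.0075) were higher in males too. Cyp2b10 had no read in injured females and was at least 1830-fold higher in males. Lrp2 was lower in males (-1.30 ± 0.22, adjusted p = 0.0029), as were Ceacam2, Ugt1a2, Serpina1f, Slc22a13 and Bhmt (-8.28 to -4.93).

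By group, NRF2 targets and iron handling gave 11 of 21 tested members higher in males, 1 higher in females and 9 not passed (13 and 2 adjusted over the list alone) (camera adjusted p = 1.7e-04, adjusted p = 0.16 with an estimated correlation). Chemokines and NF-kB targets gave 14 of 24 tested members higher in males, 0 higher in females and 10 not passed (18 and 0 adjusted over the list alone). Il34 (4.80 ± 0.43, adjusted p = 1.0e-04) and the adhesion molecule Icam1 (3.18 ± 0.50, adjusted p = 0.0020) were among its members (camera adjusted p = 3.8e-08, adjusted p = 0.33 with an estimated correlation). Male-biased kidney genes gave 15 of 17 tested members higher in males, 0 higher in females and 2 not passed (16 and 0 adjusted over the list alone) (camera adjusted p = 1.1e-13, adjusted p = 0.080 with an estimated correlation), with Slco1a1 at 512 ± 225 against 1.29 ± 1.95 CPM. Thick ascending limb and distal markers were on the female side: 0 of 11 tested members were higher in males, 7 higher in females and 4 did not pass (0 and 7 adjusted over the list alone) (camera adjusted p = 7.8e-05, adjusted p = 0.14 with an estimated correlation), with Kcnj1 (-2.84 ± 0.34, adjusted p = 5.6e-04). The distal score of these libraries was 1.01 to 1.14 in females and -1.34 to -0.28 in males. Genes of the tricarboxylic acid cycle and respiratory chain gave 0 of 25 tested members higher in males, 8 higher in females and 17 not passed (0 and 8 adjusted over the list alone). Idh2 (-0.87 ± 0.10, adjusted p = 4.8e-04) was among its members (camera adjusted p = 0.0018, adjusted p = 0.36 with an estimated correlation). Among steroid and growth hormone receptors, 0 of 16 tested members were higher in males, 5 higher in females and 11 did not pass (0 and 5 adjusted over the list alone). The mineralocorticoid receptor gene Nr3c2 (-1.70 ± 0.26, adjusted p = 0.0018) was among its members (camera adjusted p = 0.019, adjusted p = 0.33 with an estimated correlation). Sham and injured tubules shared 330 genes higher in males and 294 higher in females, where independent lists of these sizes would share 76.0 and 49.3. The authors' deposited table has 4594 genes past the threshold, 3583 of them called here. Fitting the 6 libraries alone gave 1710 genes, and leaving out injured female replicate 1, 2 or 3 gave 1912, 1996 or 2074. Leaving out injured male replicate 1, 2 or 3 gave 1921, 1884 or 8522 (without replicate 3, 3944 higher and 4578 lower in males). The distal marker covariate (chosen after seeing the data) gave 5257, of which 2519 were higher and 2738 lower in males.

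The test of the sex difference in the tubule injury response asks whether injury changed a gene differently in males and females. It called 157 genes, 70 with a higher and 87 with a lower male response. All of the 70 were also called higher after injury in males, and 71 of the 87 were called lower there. In 95 of the 157 the log2 change had opposite signs in the sexes, and in 60 it had the same sign and was larger in males. Spp1 (3.08 ± 0.31, adjusted p = 0.0033) stood at 1248 ± 138 CPM in sham females and 1823 ± 51.3 in injured females, beside 235 ± 68.6 and 2893 ± 689.7 in males. Plin2, which coats lipid droplets (4.02 ± 0.70), Gsta2 (3.24 ± 0.32), Mlkl of necroptosis (4.00 ± 0.78), Ctsl (3.26 ± 0.55) and Acsl4 (1.73 ± 0.32) also had the higher male response. The lower male response included Lrp2 (-1.61 ± 0.31, adjusted p = 0.038), Aqp3 (-2.68 ± 0.44), Kcnj1 (-2.61 ± 0.46), Esr1 (-2.09 ± 0.37), Odc1 (-1.24 ± 0.22) and the cell cycle kinase gene Cdk1 (-5.88 ± 1.05).

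Of the tubular injury list, 2 of 24 members had a higher male response over all genes and 12 adjusted over the list alone (camera adjusted p = 3.3e-06, adjusted p = 0.38 with an estimated correlation). NRF2 targets and iron handling counted 4 higher and 0 lower of 21 (9 and 1 adjusted over the list alone; camera adjusted p = 1.7e-04, adjusted p = 0.38 with an estimated correlation). Collecting duct markers counted 0 higher and 1 lower of 11 (0 and 6 adjusted over the list alone; camera adjusted p = 4.4e-05, adjusted p = 0.65 with an estimated correlation). Havcr1 (2.68 ± 1.02, adjusted p = 0.18) and Lcn2 (2.46 ± 1.43, adjusted p = 0.35) did not pass. Across all 18369 genes, which are not independent replicates, the male and female log2 changes correlated at 0.19, and at 0.53 over the 3488 genes called in males. DESeq2 called 1330 genes, the distal marker covariate (chosen after seeing the data) 4045, length offsets 59 and no filter 399. Without 1 library of the females the count was 19 to 35 (injured 1, 2, 3: 22, 19, 26, sham: 31, 35, 24). Without 1 of the males it was 55, 28 or 5892 (injured 1, 2, 3) and 25, 36 or 223 (sham 1, 2, 3). The balance of directions moved too. The male response was higher in 784 and lower in 546 genes by DESeq2, and 210 and 189 with no filter. Without sham male replicate 3 it was 58 and 165, and without injured male replicate 3 it was 2546 and 3346.

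**Figure D2:**
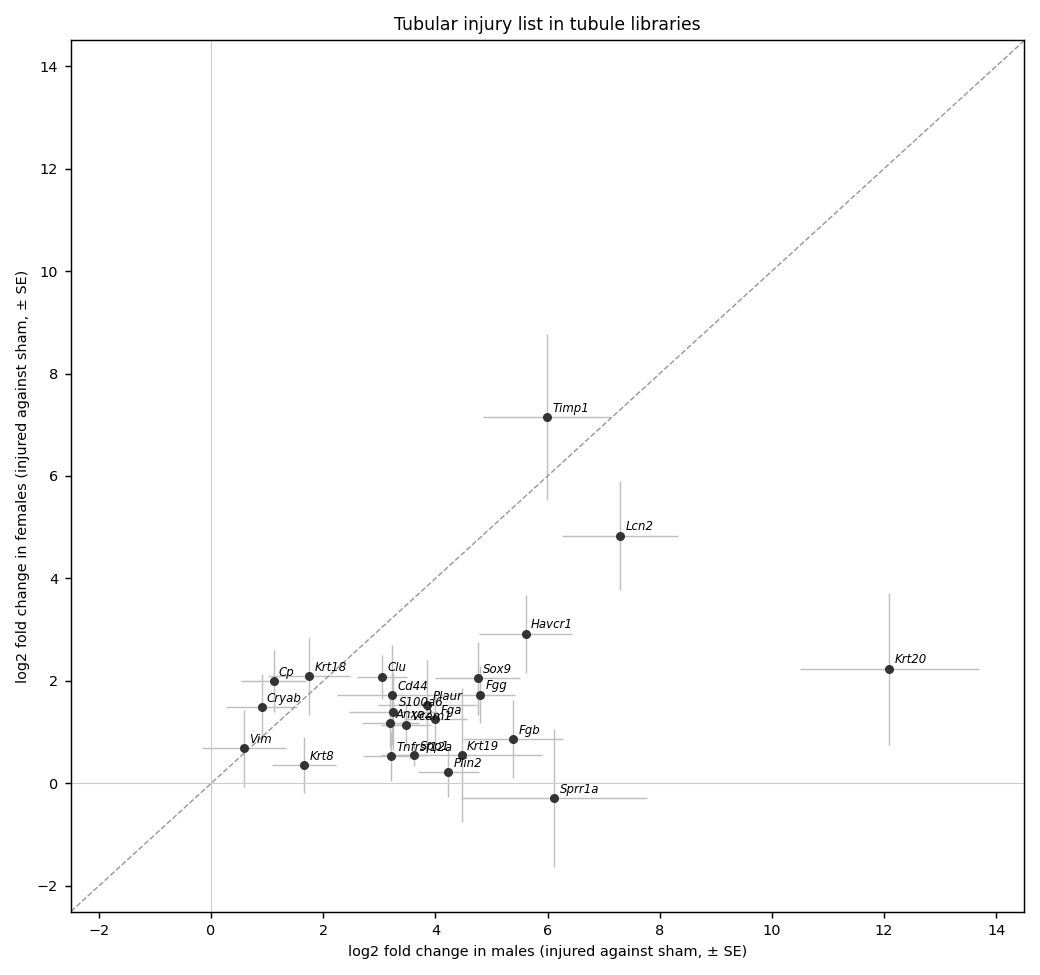
Log2 change after injury ± SE of the 24 tested tubular injury genes in proximal tubules, males on the x axis and females on the y axis, with the identity line dashed. The medians are 3.74 in males and 1.45 in females.

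Lcn2, Spp1, Krt20 and Timp1, all of the tubular injury list, rose in endothelial libraries of males. There were 107 genes higher and 65 lower after injury among 19910 tested. Lcn2 rose from 2.96 ± 0.777 to 488 ± 298 CPM (7.36 ± 0.85, adjusted p = 0.0098), and Spp1 from 663 ± 62.6 to 9109 ± 4338 (3.78 ± 0.43, adjusted p = 0.0098). Vgf, a neuropeptide precursor gene (8.90 ± 1.09), Lgi2 (6.12 ± 0.62), the decoy receptor gene Il1r2 (8.19 ± 1.64), Krt20 (10.20 ± 1.85) and Timp1 (5.80 ± 0.96) were the other rises the naming rule takes. Hao2, of peroxisomal hydroxyacid oxidation, fell from 1016 ± 549 to 127 ± 35.0 CPM (adjusted p = 0.016). Gm4952, Slc22a19, Rdh16f2, Acmsd and Hmcn2 fell with log2 changes of -3.72 to -2.47. Havcr1 (5.74 ± 1.27, adjusted p = 0.067), Pecam1 (0.32 ± 0.44, adjusted p = 0.77) and the endothelial cadherin gene Cdh5 (1.03 ± 0.64, adjusted p = 0.48) did not pass. Havcr1 read 299.6, 4.90 and 238.5 CPM in injured replicates 1, 2 and 3, and 1.26 to 4.80 in the sham males. Injured replicate 2 correlated at 0.964 and 0.967 across genes with replicates 1 and 3, which correlated at 0.997 with each other.

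For the tubular injury list, 8 of 24 tested members rose, 0 fell and 16 did not pass (21 and 0 adjusted over the list alone) (camera adjusted p = 3.7e-23, adjusted p = 0.017 with an estimated correlation). For NRF2 targets and iron handling, 6 of 21 tested members rose, 0 fell and 15 did not pass (12 and 0 adjusted over the list alone). The cystine transporter gene Slc7a11 (4.49 ± 0.66, adjusted p = 0.016) and the metallothionein gene Mt2 (4.33 ± 0.64, adjusted p = 0.016) were among its members (camera adjusted p = 1.0e-08, adjusted p = 0.20 with an estimated correlation). Chemokines and NF-kB targets read 2, 0 and 22 of 24 (22 and 0), as higher, lower and not passed, then adjusted over the list alone. Cxcl10 (2.30 ± 0.45, adjusted p = 0.045) was among its members (camera adjusted p = 1.8e-14, adjusted p = 0.20 with an estimated correlation). In that order extracellular matrix and TGF-beta targets read 2, 0 and 22 of 24 (9 and 0) (camera adjusted p = 2.4e-09, adjusted p = 0.22 with an estimated correlation). The integrated stress and ER stress response read 2, 0 and 17 of 19 (7 and 0) (camera adjusted p = 3.1e-05, adjusted p = 0.14 with an estimated correlation), and cell cycle genes 2, 0 and 25 of 27 (7 and 0) (camera adjusted p = 2.8e-09, adjusted p = 0.13 with an estimated correlation). Proximal tubule markers in these endothelial libraries read 0, 2 and 24 of 26 (0 and 13). Ttc36 (-2.23 ± 0.31, adjusted p = 0.015) was among its members (camera adjusted p = 7.1e-10, adjusted p = 0.20 with an estimated correlation). Endothelial markers read 0, 0 and 24 of 24 (0 and 0) (camera adjusted p = 0.017, adjusted p = 0.62 with an estimated correlation). MHC class II genes read 0, 0 and 7 of 7 (0 and 5) (camera adjusted p = 1.6e-05, adjusted p = 0.14 with an estimated correlation). Neutrophil markers read 1, 0 and 10 of 11 (9 and 0) (camera adjusted p = 5.1e-05, adjusted p = 0.33 with an estimated correlation). The neutrophil score was 3.65 in injured replicate 2 but 0.24 and 0.61 in replicates 1 and 3. The endothelial score was -1.16, -1.13 and 0.89 in the 3 sham males.

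Of the called genes that were tested in both isolations, 86 of 104 higher and 56 of 64 lower were called the same way in male tubules, where independent lists would share 11.2 and 5.48. These numbers take the isolations as independent, which they are not if they share mice. Among 2205 genes higher in endothelial than tubule sham libraries, 37 were called (1.68%), against 135 of 17705 others (0.762%). The authors' deposited table has 1082 genes past the threshold, 168 of them called here, and DESeq2 called 1167. The count was 61 with length offsets, 865 with no filter, 2 with the 6 libraries alone, 0 with the tubule marker covariate and 290 with the endothelial marker covariate (chosen after seeing the data). Leaving out injured replicate 1, 2 or 3 gave 47 (40 higher, 7 lower), 341 (219 and 122) or 127 (110 and 17), and leaving out sham replicate 1, 2 or 3 gave 4, 0 or 703 (353 and 350).

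In endothelial libraries of females, edgeR called 0 genes after injury (smallest adjusted p = 0.35), with n = 2 sham libraries. Lcn2 stood at 34.6 ± 24.8 CPM in injured females (3.77 ± 0.86, adjusted p = 1.0), and Spp1 at 1175 ± 288 and 3296 ± 1063 (1.49 ± 0.45, adjusted p = 1.0). For the tubular injury list, 0 of 24 tested members rose, 0 fell and 24 did not pass (5 and 0 adjusted over the list alone), with a median of 1.36 (camera adjusted p = 3.9e-12, adjusted p = 0.11 with an estimated correlation). Collecting duct markers had a median of 0.54 (camera adjusted p = 2.4e-05, adjusted p = 0.95 with an estimated correlation). At an unadjusted p under 0.05 there were 475 genes (2.39%), fewer than chance gives at that threshold. DESeq2 called 34, and the authors' deposited table has 57, among them Lcn2 (3.46 ± 0.80 in that table). No filter gave 18 genes, the 5 libraries alone 3, and leaving out sham replicate 1 gave 1. The sex difference in the endothelial response likewise gave 0 genes by edgeR (smallest adjusted p = 0.45), 1294 (6.5%) at an unadjusted p under 0.05 and 60 by DESeq2. No filter gave 44 there, and leaving out injured male replicate 2 gave 1.

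Sham endothelial libraries of males and females, with n = 3 and n = 2, differed in 55 genes higher in males and 31 higher in females. Among 2205 genes higher in endothelial than tubule sham libraries, 3 were called (0.136%), against 83 of 17705 others (0.469%). Sex differences of endothelial cells were not told apart from those of tubule RNA in these libraries. The organic anion transporter gene Slco1a1 (chromosome 6, 141907282 to 141946962) stood at 791 ± 376 CPM in males and 0.0788 ± 0.0303 in females (13.17 ± 0.91, adjusted p = 1.3e-04). Acsm3 stood at 329.8 ± 149 and 0.210 ± 0.108 (10.68 ± 0.75, adjusted p = 1.3e-04). Ddx3y, Eif2s3y and Apoh had no read in the sham females and were at least 1750-fold, 1370-fold and 415-fold higher in males. Kap, an androgen-regulated kidney gene, stood at 14500 ± 5604 against 46.0 ± 19.9 CPM, and the cytochrome gene Cyp2j13 differed by 10.30 ± 0.94. Ugt1a2 (-10.67 ± 0.78, adjusted p = 1.4e-04), Atp13a4, Prlr, Akr1c20, Slc22a29 and Bhmt were higher in females. Of male-biased kidney genes, 11 of 17 tested members were higher in males, 0 higher in females and 6 did not pass (15 and 0 adjusted over the list alone) (camera adjusted p = 8.1e-43, adjusted p = 0.014 with an estimated correlation). Of MHC class II genes, 0 of 7 tested members were higher in males, 0 higher in females and 7 did not pass (7 and 0 adjusted over the list alone), a group call that held. Cd74 (2.93 ± 0.56, adjusted p = 0.059) and H2-Ab1 (3.10 ± 0.62, adjusted p = 0.068) were among its members (camera adjusted p = 2.0e-10, adjusted p = 0.026 with an estimated correlation). Y-linked genes gave 3 of 4 tested members higher in males, 0 higher in females and 1 not passed (4 and 0 adjusted over the list alone) (camera adjusted p = 4.0e-13, adjusted p = 0.0044 with an estimated correlation). X-linked genes that escape inactivation gave 0 of 9 tested members higher in males, 1 higher in females and 8 not passed (0 and 2 adjusted over the list alone). Xist, with no read in the sham males, was at least 4370-fold lower there (adjusted p = 0.0039) and is among its members (camera adjusted p = 4.6e-04, adjusted p = 0.044 with an estimated correlation). Of these calls 51 of 55 and 28 of 31 were shared with sham tubules, where independent lists would share 1.80 and 0.807, with the same limit. The authors' deposited table has 422 genes past the threshold, 84 of them called here. DESeq2 called 385, no filter gave 250 and the tubule marker covariate 187. Leaving out sham female replicate 1 or 2 gave 25 or 25, sham male replicate 1, 2 or 3 gave 41, 35 or 218, and injured male replicate 2, outside the groups, gave 214.

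Injured endothelial libraries differed in 132 genes higher in males and 166 higher in females. Among 2205 genes higher in endothelial than tubule sham libraries, 24 were called (1.09%), against 274 of 17705 others (1.55%). Tubule RNA was not told apart here either. Slco1a1, Acsm3, Cyp2j13 and Kdm5d were again higher in males (11.30 to 6.74), and Ugt1a2, Atp13a4, Bhmt, Slc22a27, Slc22a29 and Slc22a13 in females (-8.12 to -4.99). Lcn2 stood at 488 ± 298 against 34.6 ± 24.8 CPM (3.82 ± 0.72, adjusted p = 0.026), and Slc34a1, the phosphate transporter gene, at 1657 ± 516 against 4459 ± 666 (-1.43 ± 0.29, adjusted p = 0.037). Of the tubular injury list, 3 of 24 tested members were higher in males, 0 higher in females and 21 did not pass (16 and 0 adjusted over the list alone). Tnfrsf12a (2.90 ± 0.53, adjusted p = 0.022) and Krt8 (1.78 ± 0.35, adjusted p = 0.031) were among its members (camera adjusted p = 9.1e-13, adjusted p = 0.048 with an estimated correlation). NRF2 targets and iron handling gave 7 of 21 tested members higher in males, 0 higher in females and 14 not passed (8 and 0 adjusted over the list alone). Hmox1 (2.39 ± 0.38, adjusted p = 0.012) was among its members (camera adjusted p = 1.1e-05, adjusted p = 0.29 with an estimated correlation). Male-biased kidney genes gave 10 of 17 tested members higher in males, 0 higher in females and 7 not passed (13 and 0 adjusted over the list alone) (camera adjusted p = 2.9e-20, adjusted p = 0.054 with an estimated correlation). Y-linked genes gave 4 of 4 tested members higher in males, 0 higher in females and 0 not passed (4 and 0 adjusted over the list alone) (camera adjusted p = 1.4e-10, adjusted p = 0.0092 with an estimated correlation). Proximal tubule markers gave 1 of 26 tested members higher in males, 4 higher in females and 21 not passed (1 and 12 adjusted over the list alone) (camera adjusted p = 1.0e-08, adjusted p = 0.26 with an estimated correlation). The authors' deposited table has 1050 genes past the threshold, 291 of them called here. DESeq2 called 1088 (567 higher and 521 lower in males), no filter gave 824 (478 and 346) and the tubule marker covariate 106 (70 and 36). The 6 libraries alone gave 132 (53 and 79) and the endothelial marker covariate (chosen after seeing the data) 722 (309 and 413). Leaving out injured female replicate 1, 2 or 3 gave 104, 77 or 106, and injured male replicate 1 gave 136.

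**Figure D3:**
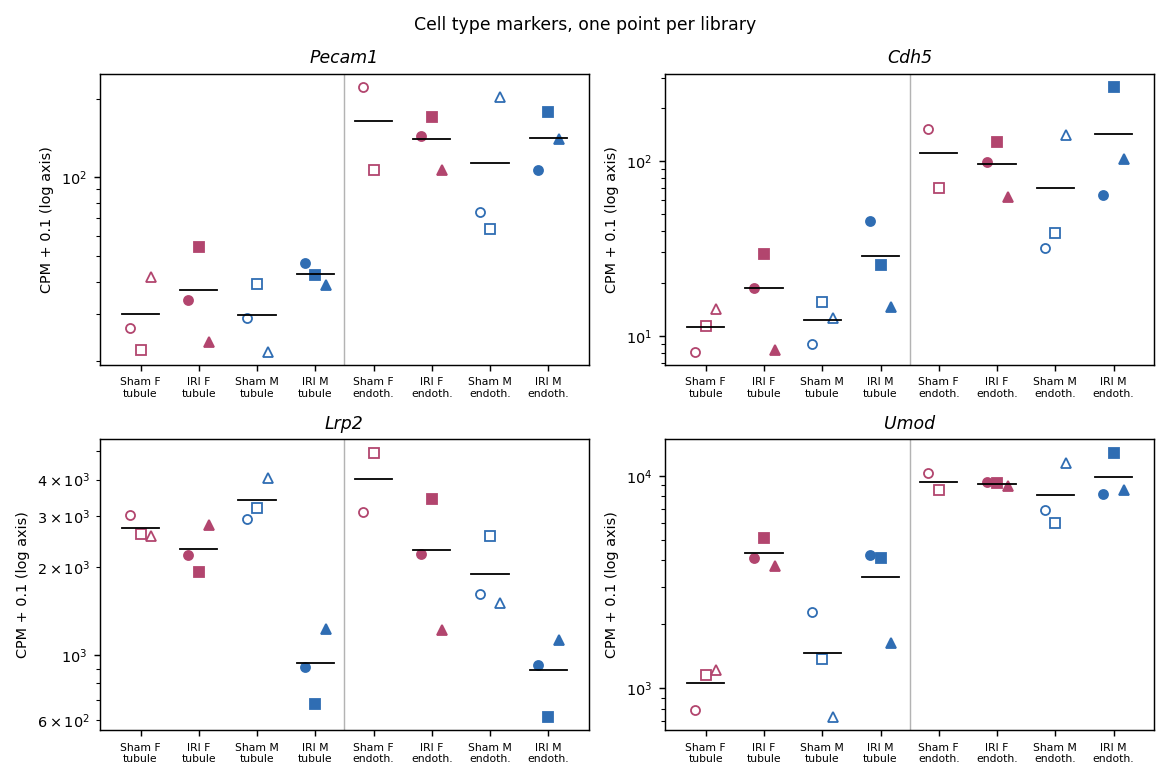
CPM + 0.1 (log axis) of 4 cell type markers in each library of both isolations; open points are sham, filled points injured, pink female, blue male, and black lines mark group means. Pecam1 and Umod are higher in endothelial than in tubule libraries, while the Lrp2 values of the isolations overlap.

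Sham endothelial libraries were compared with sham tubule libraries; no whole kidney library was among the samples, so levels are relative to dissected tubules. Endothelial genes were higher in the endothelial libraries: Pecam1 averaged 2.07 ± 0.32 on the log2 scale above tubule (adjusted p = 2.9e-04) and Cdh5 2.80 ± 0.47. Of endothelial markers, 22, 0 and 2 of 24 (22 and 0) were higher, lower and not passed, then adjusted over the list alone (camera adjusted p = 7.6e-19, adjusted p = 0.39 with an estimated correlation). Genes of other kidney cells were higher in the endothelial libraries as well. Umod, of the thick ascending limb, was at 8105 ± 2940 CPM in male and 9398 ± 1211 in female (n = 2) sham endothelial libraries (2.69 ± 0.29, adjusted p = 3.3e-05). In the same order podocyte markers read 7, 0 and 3 of 10 (9 and 0) (camera adjusted p = 1.8e-06, adjusted p = 0.39 with an estimated correlation), with Podxl (2.55 ± 0.52, adjusted p = 0.0028). Thick ascending limb and distal markers read 5, 0 and 6 of 11 (5 and 0) (camera adjusted p = 3.7e-04, adjusted p = 0.39 with an estimated correlation), and collecting duct markers 4, 0 and 7 of 11 (7 and 0) (camera adjusted p = 0.0010, adjusted p = 0.44 with an estimated correlation). Stromal and mural markers read 5, 1 and 9 of 15 (5 and 3) with a negative median although their test pointed up. Pdgfrb (3.38 ± 0.64, adjusted p = 0.0014) and Des (3.81 ± 0.61, adjusted p = 3.9e-04) were among its members (camera adjusted p = 0.38). Vascular tone and quiescence genes read 13, 2 and 7 of 22 (15 and 2). Tie1 (2.54 ± 0.39, adjusted p = 2.7e-04) was among its members (camera adjusted p = 6.6e-05, adjusted p = 0.39 with an estimated correlation). Proximal tubule transcripts stayed abundant: Lrp2 differed by -0.28 ± 0.25 (adjusted p = 0.55), and proximal tubule markers read 1, 1 and 24 of 26 (1 and 1) (camera adjusted p = 1.2e-04, adjusted p = 0.39 with an estimated correlation). Under the naming rule, which asks for 5 CPM and no overlap between groups, the largest excesses in endothelial libraries were Sost, Gata5, Fst, Kcnj5, Lgr5 and Sfrp2 (5.14 to 4.38), and the largest in tubule were Slc22a7, Id1, G0s2, Slc25a25, Akr1c18 and Errfi1 (-2.94 to -1.45). In all, 2208 genes were higher and 395 lower in endothelial libraries among 21206 tested. Leaving out sham female endothelial replicate 1 gave 1388 genes and sham male endothelial replicate 3 gave 1700.

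The injury response itself, averaged over the sexes, was then compared between the isolations. No gene differed by edgeR (0 called, smallest adjusted p = 0.40), and DESeq2 called 23. An unadjusted p under 0.05 was reached by 1011 genes (4.77%), no more than chance gives at that threshold. Slc12a1, Umod and Cldn16 had the lowest p among thick ascending limb and distal markers, with endothelial minus tubule responses of -1.73 ± 0.47, -1.50 ± 0.38 and -1.43 ± 0.29 (camera adjusted p = 8.9e-07, adjusted p = 0.12 with an estimated correlation). Across 18056 genes the male responses of the isolations correlated at 0.67 with 79.7% of signs shared, and the female responses at 0.17 with 51.5%. Over the 3483 genes called in male tubules the male responses correlated at 0.91, with 98.8% of signs shared. No filter and leaving out sham female tubule replicate 3 each gave 1 called gene.

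**Figure D4:**
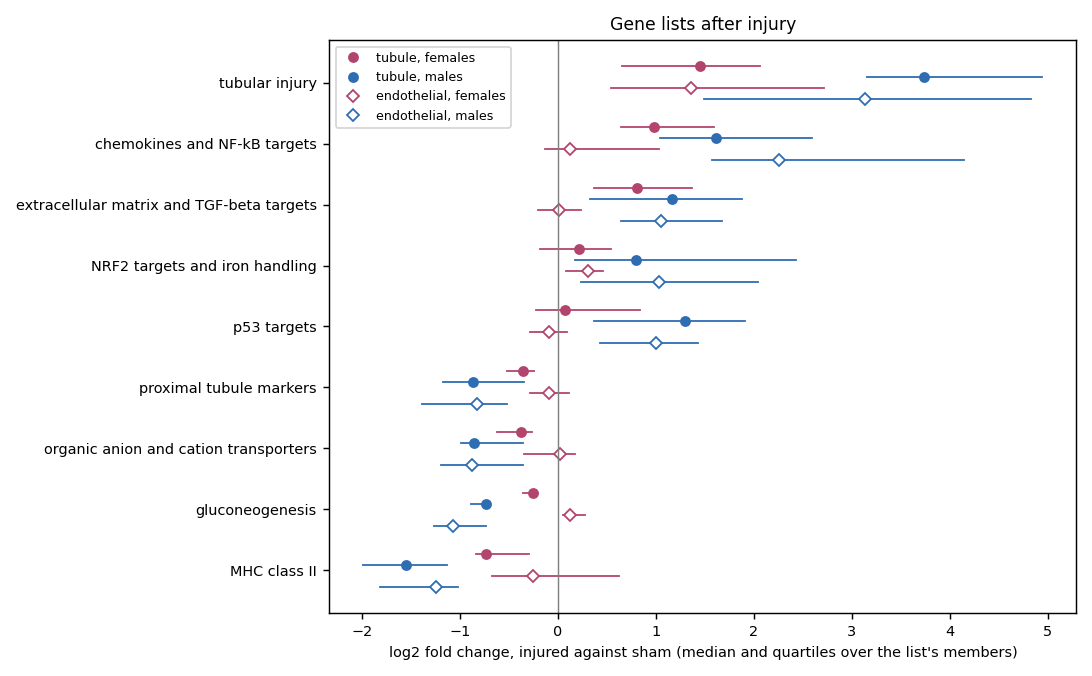
Median log2 change after injury (x axis, points) and quartiles (bars) of 9 gene lists in the 4 sex and isolation comparisons. The tubular injury list has medians of 3.74 and 3.14 in male tubule and endothelial libraries and 1.45 and 1.36 in the female ones.

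Across the 12 comparisons and 40 lists, 189 of 480 camera tests passed with the preset correlation and 8 with the estimated one. Those 8 were male-biased kidney genes in sham tubule and sham endothelial libraries, the tubular injury list in male endothelial libraries after injury and in injured endothelial libraries by sex, Y-linked genes in both endothelial sex comparisons, and MHC class II and X-linked escape genes in sham endothelial libraries.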

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

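The tests of swapped numbers, a sham library among injured males, depth, spread borrowed from males, distal RNA, a smaller change in females and uneven endothelial yield were chosen after the result was seen. The tests of tubule RNA, carried-over RNA and other splits were written before. The test of single libraries far from the others is set for groups of 4 to 10, and the groups hold 2 or 3, so it was not run.

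The results below stand out because injury changed a gene differently in males and females by the interaction test. It called 157 genes in tubules, and 1 of 60 splits of the libraries, the real one, gave as many, the highest other giving 34. The other splits mix males and females within groups, so the sex difference itself widens their spread. Their counts can be small with or without a sex difference in the response, so the splits do not decide on chance. Values are the male minus the female log2 change. Among genes of at least 5 CPM, as the naming rule asks, the largest on the male side were Adra1b 8.10, Gsta1 6.01, Lrp8 5.55, Hdc 4.95, Gm10639 4.16 and Eps8l3 4.03. Under the same rule the largest on the female side were Gvin1 -10.20, Slc2a13 -3.21, Ipcef1 -3.19, Lrrc66 -2.94, Wscd1 -2.91 and Pdgfd -2.91. Given as male then female log2 change ± SE, Adra1b, encoding an adrenergic receptor, stood at 7.33 ± 1.20 and -0.77 ± 0.94, Lrp8 at 4.94 ± 0.80 and -0.61 ± 0.68, Hdc at 3.48 ± 0.75 and -1.47 ± 0.66 and Eps8l3 at 3.15 ± 0.44 and -0.88 ± 0.43. In the same order Slc2a13 stood at -0.95 ± 0.40 and 2.25 ± 0.42, Ipcef1 at -1.36 ± 0.29 and 1.82 ± 0.29, Lrrc66 at -1.38 ± 0.39 and 1.56 ± 0.39, Wscd1 at -1.57 ± 0.33 and 1.34 ± 0.33 and Pdgfd at -1.38 ± 0.36 and 1.52 ± 0.37. By edgeR none of the female changes of the 12 genes passed (adjusted p = 0.057 to 0.90), and of the male ones those of Slc2a13 (adjusted p = 0.11) and Gvin1 (adjusted p = 0.93) did not. The distal marker score also parted injured females (1.01 to 1.14) from sham females (0.06 to 0.16). Whether RNA of other nephron segments gave the female changes of these genes was not tested gene by gene. Gsta1 (5.36 ± 0.80 and -0.65 ± 0.66), Gm10639 (3.42 ± 0.48 and -0.74 ± 0.43) and Gvin1 (0.11 in males) have close paralogs, and how reads were shared among them was not tested. Gvin1 had no read in the sham females and was at least 139-fold higher in the injured ones, so the size of its difference is set by the prior count. Adra1b averaged 0.041 CPM in sham males, so the size of its difference is uncertain too. Gsta1 varied widely among injured males (64.2 ± 79.9 CPM). Hdc, also a member of the neutrophil list, was at 12.1 ± 9.80 CPM in injured males and 33.7 ± 11.5 in injured females.

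The first pattern weighed is that injured male libraries differ among themselves: without tubule replicate 3 the male injury count went from 3488 to 8203 genes. A test of swapped replicate numbers decides nothing (best assignment of endothelial to tubule libraries, lowest correlation -0.4853), since the isolations are not known to share mice. A sham library among the injured males is argued against, since the lowest injured male library exceeded the highest sham male by 2.4251 log2 CPM on the tubular injury list. Depth is argued against, since the deepest held 1.23 times the reads of the shallowest. A difference between mice in the extent of injury may remain, which was not tested.

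The second pattern is that fewer tubule genes were called for injury in females (2) than in males (3488). Spread borrowed from the male libraries is consistent with the counts, since the females fitted alone gave 1167 genes and the males alone 154. A smaller change in females is consistent with them too, since the median of the tubular injury list was 2.0579 lower in females even with injured male replicate 3 left out. Distal RNA in the injured female libraries stays open: with the distal score as a covariate 0 genes were called in females and 4045 for a sex difference in the response, but the score parts injured from sham females (1.01 to 1.14 against 0.06 to 0.16), and leaving out injured male replicate 3, whose score of -1.34 is the lowest, gave 5892 for that difference. These explanations may hold together, and a biological difference between the sexes stays open as untested.

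The third pattern is the 172 genes called for injury in male endothelial libraries, whose changes resembled those in tubules. Tubule RNA was present in the endothelial libraries: in sham, Slc34a1 was at 2689 to 5196 CPM there and 4486 to 6276 in tubule. Whether it gave these calls stays open. Genes higher in endothelial sham libraries were called 2.2 times as often as the others, but that bound was wrong. The set holds 21 other epithelial, podocyte and stromal markers beside 22 endothelial ones. Of its called genes tested in tubule, 36 of 36 moved the same way there, 29 of them called. Carried-over RNA stays open: 52.9% of genes called higher (55 of 104, exact 95% interval 42.8 to 62.8) rose by more CPM in endothelial than in tubule libraries. The rule written before took any majority as going against it, but the interval also holds values short of a majority. That interval takes the genes as independent, which they are not. CPM were also normalized separately in each isolation, so the rises may not share a scale, and the test does not decide. Uneven endothelial yield stays open. With the endothelial score as a covariate 290 genes were called, which goes against it, but with the tubule marker score 0 were called. The tubule score ran opposite to the endothelial score in sham males 1, 2 and 3 (0.57, 0.64 and -0.34). It also parts them from the injured males (-1.10 to -0.51), so that fit cannot decide. Leaving out sham replicate 1, 2 or 3 gave 4, 0 or 703 genes. A response of the endothelial cells themselves may also contribute, and was not told apart from these.

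For 6 comparisons only 10 splits exist, too few for a share under 5%. The real count and the highest other were 2 and 0 for injury in female tubules, 3488 and 1 in male tubules, 1065 and 0 for sex in sham tubules, 4271 and 0 for sex in injured tubules, 172 and 0 for injury in male endothelial libraries, and 298 and 1 for sex in injured endothelial libraries, where in each case 1 of the 10 reached the real count. For endothelial against tubule in sham, 1 of 40 splits gave 2603, the real one, and the highest other gave 1262. The other splits mix the isolations within groups, so the difference between isolations itself widens their spread. These splits therefore do not decide on chance either. For the response compared between isolations, the real count is 0, so 40 of 40 splits reach it by construction and the test says nothing about chance. The highest other count was 3430.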

How the results depend on the processing

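The fits with the distal or endothelial marker covariate, and those leaving out injured male tubule replicate 3 or endothelial replicate 2 from comparisons they are not part of, were chosen after seeing the data. Counts of called genes are given as the value under the alternative, and the cause was not tested. Injury in female tubules (2): 635 by DESeq2, 158 with no filter, 0 with length offsets, 0 with the distal covariate, 1167 with only its groups, leave-one-out 0 to 501. Injury in male tubules (3488): 2115 with length offsets, 5983 with the distal covariate, 154 with only its groups, leave-one-out 953 to 8203. Sex in sham tubules (1065): 1950 by DESeq2, 1709 with only its groups, leave-one-out 550 to 2626. Sex in injured tubules (4271): 1710 with only its groups, leave-one-out 1884 to 8522. Sex difference in the tubule response (157): 1330 by DESeq2, 399 with no filter, 59 with length offsets, 4045 with the distal covariate, leave-one-out 19 to 5892. Injury in female endothelial libraries (0): 34 by DESeq2, 18 with no filter, 3 with only its groups, leave-one-out 0 to 1. Injury in male endothelial libraries (172): 1167 by DESeq2, 865 with no filter, 61 with length offsets, 2 with only its groups, 0 with the tubule covariate, 290 with the endothelial covariate, leave-one-out 0 to 703. Sex in sham endothelial libraries (86): 385 by DESeq2, 250 with no filter, 187 with the tubule covariate, leave-one-out 25 to 218. Sex in injured endothelial libraries (298): 1088 by DESeq2, 824 with no filter, 132 with only its groups, 106 with the tubule covariate, 722 with the endothelial covariate, leave-one-out 77 to 386. Sex difference in the endothelial response (0): 60 by DESeq2, 44 with no filter, leave-one-out 0 to 1. Endothelial against tubule in sham (2603): leave-one-out 1388 to 2676. Response between isolations (0): 23 by DESeq2, 1 with no filter, leave-one-out 0 to 1. Gene list tests past the threshold went from 189 to 8 with the estimated correlation. With RLE each of the 12 counts stayed within 1.5 times. Where a sham female endothelial library is left out, the lone sample is assumed to vary like the other groups. The replicate block changed injury in female tubules to 1, the tubule sex difference in the response to 54, injury in male endothelial libraries to 51 and sex in injured endothelial libraries to 133. The correlations did not show that the numbers pair the samples: only 7 of 18 tubule pairs, 4 of 15 endothelial pairs and 5 of 11 pairs of the same title number between isolations correlated above 0.1. Deviations from the means of 2 or 3 libraries cannot show the reverse either, so shared mice stay possible. The 247 gene results named in the text had 3744 refits. Of these, 3132 kept their side of the threshold, 533 kept the direction but no longer passed, 79 newly passed and 0 reversed. A change of sign counted as reversed only if a fit called the gene. Sign changes of genes called in neither fit would be among the 3132. Of those no longer passing, 360 came with a library left out, 65 with only the groups compared, 33 with the replicate number as block, 31 with length offsets, 24 with the tubule covariate, 7 with the distal covariate, 5 with the second technical library not added, 4 with DESeq2, 3 with the endothelial covariate and 1 with RLE. Depth limits small changes: the genes listed at 0 in a group lie below 0.0212 to 0.0317 CPM.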

Other observations

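Further lists in injured male tubules, where 19.0% of all genes were called, are given as higher, lower and not passed of those tested, then adjusted over the list alone. Hypoxia and glycolysis genes read 6, 1 and 13 of 20 (6 and 1) (camera adjusted p = 0.069), with Pfkp (1.89 ± 0.35, adjusted p = 0.0068) of glycolysis and the glucose carrier gene Slc2a1 (2.97 ± 0.71, adjusted p = 0.019). Apoptosis regulators read 6, 1 and 13 of 20 (8 and 2) (camera adjusted p = 0.16), with Bcl2l1 (1.73 ± 0.32, adjusted p = 0.0071) and Casp8 (0.86 ± 0.20, adjusted p = 0.017), and necroptosis and pyroptosis genes 1, 0 and 8 of 9 (2 and 0) (camera adjusted p = 0.075), with Mlkl (3.85 ± 0.58, adjusted p = 0.0027). Immediate early genes read 4, 0 and 15 of 19 (4 and 0) (camera adjusted p = 0.0059, adjusted p = 0.62 with an estimated correlation), with Fosl2 (2.37 ± 0.57, adjusted p = 0.019), and heat shock genes 4, 2 and 7 of 13 (4 and 4) (camera adjusted p = 0.61), with Hspb1 (3.32 ± 0.76, adjusted p = 0.015) higher and Dnaja1 (-0.79 ± 0.14, adjusted p = 0.0055) lower. Cholesterol synthesis genes read 2, 5 and 11 of 18 (4 and 5) (camera adjusted p = 0.45), with Idi1 (-1.77 ± 0.32, adjusted p = 0.0057). Interferon-stimulated genes read 3, 1 and 17 of 21 (4 and 1) (camera adjusted p = 0.11), with Rsad2 (4.03 ± 1.03, adjusted p = 0.023), and complement and coagulation genes 4, 0 and 16 of 20 (5 and 0) (camera adjusted p = 0.031, adjusted p = 0.46 with an estimated correlation), with F3 (3.03 ± 0.84, adjusted p = 0.030), the tissue factor gene. Endothelial activation and leukocyte adhesion genes read 3, 1 and 10 of 14 (4 and 1) (camera adjusted p = 0.088), with Edn1 (2.45 ± 0.48, adjusted p = 0.0084), and steroid and growth hormone receptors 0, 5 and 11 of 16 (0 and 5) (camera adjusted p = 0.0011, adjusted p = 0.24 with an estimated correlation), with Ghr (-0.91 ± 0.17, adjusted p = 0.0061).

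Blood cell markers of sham endothelial against sham tubule libraries are given in the same order. Lymphocyte markers read 6, 0 and 8 of 14 (7 and 0) (camera adjusted p = 1.8e-04, adjusted p = 0.39 with an estimated correlation), with Cd79a (6.58 ± 1.26, adjusted p = 0.0021) of B cells, erythroid markers 3, 0 and 2 of 5 (5 and 0) (camera adjusted p = 0.0071, adjusted p = 0.41 with an estimated correlation), macrophage and monocyte markers 2, 0 and 14 of 16 (2 and 0) (camera adjusted p = 0.11), with Mrc1 (3.15 ± 0.43, adjusted p = 1.1e-04), and platelet markers 0, 0 and 6 of 6 (0 and 0) (camera adjusted p = 0.34).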
